A study of Mus musculus with 79 samples.

How the data were processed

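RNA was sequenced from liver, kidney and lung of 16 C57BL/6 mice kept in a light-dark cycle and from liver of WT and Per1,2 double knockout mice kept in constant darkness for 2 days, 79 libraries in 20 groups. Per the labels' protocols, mice aged 3 months breathed 6% or 21% oxygen for 4 h, tissues were snap-frozen, total RNA was extracted with a phenol reagent, cDNA amounts were evened by quantitative PCR of actin, and indexed cDNA was pooled and amplified linearly by in vitro transcription before fragmentation. Per the series design text among the labels, replicates of a group are separate mice.

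The values used here are raw counts per gene symbol as deposited by the authors, 1 table per tissue in the light-dark part and 1 per genotype in constant darkness. The submitters' processing notes name bcl2fastq, cutadapt, STAR, HTSeq and the genome build mm10, and their versions, the gene annotation and the strand setting are not given in the sources used here. Without strand, counts of a gene and its antisense partner cannot be told apart. Raw reads were not used here. The smallest highest count of any listed gene was 6 in each table, and genes counted less often were not listed. Of 15198 symbols, 14647 matched GENCODE vM21 by name and 443 through a RefSeq synonym, and 15061 took 1 position on mm10.

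Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM within each fit (CPM use the scaled totals), and the quasi-likelihood test with robust dispersion was adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The 4 groups of a table shared 1 fit, WT and KO in constant darkness shared a joint fit, and the tissues of the light-dark mice shared a fit with mouse as a block. The design text gives 3 tissues per mouse but not which libraries share one, so matching time, oxygen level and replicate letter was taken to mark a mouse. These gave 27 comparisons: 6% against 21% oxygen in each of 10 tissue, time and genotype settings, its difference between times, genotypes and tissues, and the differences between times and between genotypes in air. Interactions were fitted directly. Genotype and table coincide, so a batch shift enters genotype in air, but the response only if the shift differs by oxygen.

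For each of 35 gene lists, limma 3.58.1 camera tested the measured members against all other genes, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists, where at least 3 members were measured. Counts of called members are also given adjusted over the list alone. The comparisons, tests, lists and alternatives were fixed before the data were examined, except those stated to have been added later. Named genes followed a fixed rule. For oxygen, up to 6 rises and 6 falls were taken by fold change among called genes with a mean of at least 10 CPM, no overlap between groups and no placeholder symbol. For the differences between times in air, up to 4 each way were taken. For interactions, genotype and tissue, up to 8 genes were taken by smallest adjusted p. Up to 4 members per described list were taken by smallest p, and 9 genes (Arntl, Per1, Per2, Cry1, Nr1d1, Dbp, Hif1a, Vegfa and Pck1) anywhere. The chance overlap of called genes is the product of both counts divided by the genes tested in both, per direction.

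Total counts ran from 1.44 to 6.74 M per library, with a median of 3.02 M. In KO liver the 6% libraries were deeper than the air libraries, 2.25 ± 0.22 against 1.77 ± 0.14 M at CT4-8 and 3.42 ± 0.54 against 1.74 ± 0.28 M at CT16-20 (exact two-sided permutation p = 0.029 in each, adjusted p = 0.14). No within-group pair of libraries was a copy: chi-square per degree of freedom ran from 2.31 to 31.3 over 117 pairs, and 0 pairs were identical. In data simulated from these libraries with 200 changed genes, over 18 comparisons, 19 to 76% of true log2 changes of 1 and 77 to 98% of changes of 2 were called, with 1.28 to 7.53% false calls. A list shifted on purpose was called in all 18, with at most 2 other lists called. The simulated genes were drawn independently, without the correlation between members that real lists have. The number of false list calls in the real data is therefore not measured by it.

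Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a replicate block (or none for tissues), fits on only the libraries compared, a threshold of 0.01 for overlaps, and leaving out each library or mouse in turn. Fits without 3 lung control libraries or their mice, and counts thinned to the smallest library total of the constant-dark tables, 1.44 M, were added after seeing the data. No per-sample column of the tables was left unused. Some genes that the naming rule takes are not reported here.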

Results

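RNA was sequenced from liver, kidney and lung of C57BL/6 mice aged 3 months that had breathed 6% oxygen, or 21% oxygen as control, for 4 h in a cage flushed with a constant gas flow. In the light-dark (LD) part, 16 wild-type mice kept in 12 h of light and 12 h of darkness were exposed either in the light phase (zeitgeber time, ZT, 4 to 8 h) or in the dark phase (ZT16-20). Liver, kidney and lung were taken from each mouse. In the constant-darkness (DD) part, liver was taken from wild-type (WT) mice and from mice labelled Per1,2 double knockout (KO). The label names a pair of light-responsive repressors of the circadian clock. WT and KO mice were exposed at circadian time (CT) 4 to 8 h or 16 to 20 h. The 79 libraries formed 20 groups of 4, except KO mice at CT16-20 in 6% oxygen with 3. Total counts per library ran from 1.44 to 6.74 M with a median of 3.02 M. They spanned 3.01 to 6.74 M in LD liver, 2.15 to 3.91 M in kidney and 1.65 to 4.35 M in lung. In darkness they spanned 1.65 to 2.97 M in WT and 1.44 to 3.77 M in KO liver.

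Values for genes are log2 fold changes ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test. Group levels are CPM, counts scaled to library totals adjusted by TMM, as mean ± SD, with n = 4 unless stated. Libraries were scaled within each fit, so the levels of Tat beside the comparison of genotypes, from the joint fit, differ slightly from those of the single tables. A gene is called, and written as having risen or fallen, at an adjusted p under 0.05. Counts of list members are given as higher or lower of those measured, beside the count adjusted over the list alone. The adjusted p beside a list is that of a set test (limma's camera) with a preset correlation. That set test also passed with an estimated correlation wherever no second adjusted p is printed beside a passing one. Members of gene families such as Acot, Cyp2, Cyp3, Cyp4, Ces, Gst, Hspa1, Mt, Mup and Saa share sequence with close copies, so their values are uncertain. Genes that overlap others, or have antisense partners, are uncertain too.

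In air, the targeted genes did not separate the libraries by label. Per1 stood at 28.8 ± 6.66 CPM at CT4-8 and 28.7 ± 5.62 at CT16-20 in libraries labelled KO, against 26.3 ± 10.7 and 42.2 ± 9.29 in WT. Per2 stood at 8.39 ± 3.19 and 7.38 ± 2.98 CPM in libraries labelled KO, against 8.25 ± 2.00 and 13.2 ± 3.35 in WT. At 6% oxygen, Per1 did not overlap between the labels, with 14.9 to 21.2 CPM in KO and 44.9 to 84.7 in WT at CT4-8, and 15.7 to 31.3 and 61.5 to 76.7 at CT16-20. Per2 stood at 19.0 to 30.9 in KO and 2.92 to 10.8 in WT at CT4-8, and overlapped at CT16-20 with 20.2 to 32.1 and 7.90 to 29.1. The labels do not give the deleted part of either gene, and counts per gene symbol from outside it check nothing, so genotype is used here as labelled. In air Dbp, a clock-driven transcription factor, did separate the labels. It fell from 232 ± 27.9 CPM at CT4-8 to 9.91 ± 2.16 at CT16-20 in WT air libraries but stood at 102 ± 17.2 and 80.5 ± 30.1 in libraries labelled KO.

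The first question was how 4 h of low oxygen changed each tissue in the light and in the dark phase. In liver at ZT4-8, Ddit4, an inhibitor of mTORC1 (mm10, chromosome 10, 59949669 to 59951834), rose from 4.67 ± 3.65 to 334 ± 111 CPM (6.05 ± 0.92, adjusted p = 0.00084). Gdf15, a stress-induced hormone (5.75 ± 0.46), Hilpda, an inhibitor of lipolysis (5.48 ± 0.33), the stress transcription factor Atf3 (5.63 ± 0.87) and Gadd45b (5.13 ± 0.44) followed. Among the deepest falls were Dbp (-2.74 ± 0.35, adjusted p = 0.00011), the pioneer factors of hepatocyte identity Foxa2 (-2.53 ± 0.31) and Foxa1 (-2.26 ± 0.35), Inhbe (-2.63 ± 0.28) and the thioesterase gene Acot3 (-3.24 ± 0.72). Of 9451 genes tested, 911 were called, 513 higher and 398 lower at 6% oxygen.

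Immediate early genes rose together in liver at ZT4-8 (13 of 16 measured higher, 13 adjusted over the list alone, adjusted p = 1.6e-30), with Ier3 at 3.89 ± 0.26 and Btg2 at 3.90 ± 0.34. Glycolytic genes did so as well (8 of 13 measured higher, 8 adjusted over the list alone, adjusted p = 4.8e-06), led by the glucose transporter gene Slc2a1 (1.92 ± 0.21) and Pfkfb3 (2.27 ± 0.24). The other targets of the hypoxia-inducible factors (HIF) included Ankrd37 (4.27 ± 0.34), Cited2 (3.32 ± 0.25) and the angiogenic factor gene Vegfa (1.51 ± 0.15). This list rose (9 of 20 measured higher, 11 adjusted over the list alone, adjusted p = 9.0e-19). Hif1a itself was not called (-0.15 ± 0.42, adjusted p = 0.88). Genes induced by glucocorticoids rose (10 higher and 1 lower of 17 measured, 10 and 1 adjusted over the list alone, adjusted p = 2.4e-18). Among them were the cell cycle inhibitor gene Cdkn1a (4.83 ± 0.23), the tyrosine catabolism gene Tat (2.09 ± 0.19) and Sgk1 (1.89 ± 0.19). Gluconeogenesis and fasting genes rose (8 of 12 measured higher, 8 adjusted over the list alone, adjusted p = 1.3e-14), with Igfbp1 at 5.08 ± 0.41 and G6pc, the last step of glucose release, at 1.70 ± 0.20. Pck1 was not called (0.32 ± 0.21, adjusted p = 0.40). Genes of the integrated stress response were also higher (5 higher and 1 lower of 11 measured, 7 and 1 adjusted over the list alone, adjusted p = 1.3e-07). So were p53 targets (4 of 12 measured higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 1.9e-08). Heat shock genes fell (4 of 16 measured lower, 7 adjusted over the list alone, adjusted p = 2.3e-06), with Hsph1 at -1.88 ± 0.22 and Hspa8 at -0.92 ± 0.17. Fatty acid oxidation genes were lower as a list (1 higher and 10 lower of 24 measured, 1 and 14 adjusted over the list alone, adjusted p = 1.0e-06, adjusted p = 0.18 with an estimated correlation). Ppara, their main regulator, stood at -1.48 ± 0.13, with the pyruvate dehydrogenase kinase gene Pdk4 moving the other way (3.63 ± 0.43). Cholesterol synthesis genes (4 of 20 measured higher, 5 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation) included a rise of Insig1 (0.99 ± 0.21). Bile acid genes (3 higher and 3 lower of 14 measured, 3 and 4 adjusted over the list alone, adjusted p = 0.81) went both ways. Examples were Nr0b2, a repressor of bile acid synthesis, higher (1.77 ± 0.27) and Cyp7a1, its rate-limiting enzyme, lower (-1.36 ± 0.25).

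In liver at ZT16-20, Hilpda rose from 11.7 ± 4.82 to 463 ± 77.9 CPM (5.27 ± 0.32, adjusted p = 1.9e-08) and the clock-controlled repressor gene Ciart by 5.40 ± 0.43. Foxa2 (-3.03 ± 0.32), Foxa1 (-2.15 ± 0.32), Rsrp1 (-2.66 ± 0.15), Mettl20 (-2.29 ± 0.33) and Bok (-2.18 ± 0.18) fell. In total 1915 of 9451 genes were called, 943 higher and 972 lower. Cholesterol synthesis genes rose (12 of 20 measured higher, 14 adjusted over the list alone, adjusted p = 2.1e-11), with Insig1 at 2.29 ± 0.21. Fatty acid synthesis genes were higher (10 of 18 measured higher, 11 adjusted over the list alone, adjusted p = 1.8e-07, adjusted p = 0.20 with an estimated correlation), led by their regulator Srebf1 (3.29 ± 0.24) and with Elovl6 at 1.55 ± 0.22. Immediate early genes rose again (12 of 16 measured higher, 13 adjusted over the list alone, adjusted p = 1.4e-20), as did other HIF targets (11 higher and 2 lower of 20 measured, 11 and 2 adjusted over the list alone, adjusted p = 5.1e-13). Glycolytic genes rose (7 of 13 measured higher, 8 adjusted over the list alone, adjusted p = 6.3e-07), and so did genes induced by glucocorticoids (11 of 17 measured higher, 11 adjusted over the list alone, adjusted p = 7.1e-11). The integrated stress response rose (5 of 11 measured higher, 6 adjusted over the list alone, adjusted p = 3.9e-05). Gluconeogenesis and fasting genes rose (7 higher and 1 lower of 12 measured, 8 and 1 adjusted over the list alone, adjusted p = 3.9e-05), as did p53 targets (5 higher and 1 lower of 12 measured, 7 and 2 adjusted over the list alone, adjusted p = 6.4e-05). Clock genes rose as a list (8 higher and 2 lower of 16 measured, 8 and 2 adjusted over the list alone, adjusted p = 0.00038). Ciart, Bhlhe40 (2.26 ± 0.20) and Per1 (1.93 ± 0.44) rose, but Arntl, the positive arm of the clock, fell (-0.94 ± 0.19). Heat shock genes were lower (6 of 16 measured lower, 6 adjusted over the list alone, adjusted p = 0.0071, adjusted p = 0.064 with an estimated correlation), with Hspa1b at -1.19 ± 0.22. Fatty acid oxidation genes were lower (2 higher and 9 lower of 24 measured, 2 and 11 adjusted over the list alone, adjusted p = 0.0071, adjusted p = 0.58 with an estimated correlation), with Ppara at -1.14 ± 0.13. Bile acid genes were lower (4 of 14 measured lower, 5 adjusted over the list alone, adjusted p = 0.023, adjusted p = 0.38 with an estimated correlation), with the uptake transporter gene Slco1a1 at -0.74 ± 0.14.

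The second question was whether the response depended on the phase of the day, tested as the log2 fold change at 6% oxygen at ZT16-20 minus that at ZT4-8. In liver, 195 of 9451 genes differed, 77 with the response higher and 118 lower in the dark phase (299 by DESeq2). Arntl rose at ZT4-8 (2.91 ± 0.28) and fell at ZT16-20 (-0.94 ± 0.19), a difference of -3.85 ± 0.34, adjusted p = 3.6e-07. Clpx (-2.38 ± 0.21), Spon2 (-2.64 ± 0.23), Eps8l2 (-1.82 ± 0.17), Bok (-2.64 ± 0.25), Enpp3 (-1.91 ± 0.21) and Cdkn1a (-2.95 ± 0.29) also had the lower log2 fold change in the dark phase. Bok averaged 18.6 CPM in air and 25.3 at 6% oxygen at ZT4-8, without a call, and fell from 53.6 to 11.8 at ZT16-20. Dbp differed in the opposite sense (3.94 ± 0.52, adjusted p = 0.00069), falling in the light phase from a high level. Among clock genes (4 higher and 2 lower of 16 measured, 6 and 2 adjusted over the list alone, adjusted p = 0.029, adjusted p = 0.21 with an estimated correlation) the difference thus went both ways. Cholesterol synthesis genes had the higher response in the dark phase (3 of 20 measured higher, 8 adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.21 with an estimated correlation), with Insig1 at 1.30 ± 0.30. So did fatty acid synthesis genes (2 of 18 measured higher, 8 adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.34 with an estimated correlation), with Elovl6 at 2.13 ± 0.31. Drug metabolism genes shared that sign (1 of 23 measured higher, 4 adjusted over the list alone, adjusted p = 0.0043, adjusted p = 0.21 with an estimated correlation), with Por at 1.68 ± 0.21. Gluconeogenesis and fasting genes had the opposite one (1 of 12 measured lower, 3 adjusted over the list alone, adjusted p = 0.0034, adjusted p = 0.21 with an estimated correlation). So did bile acid genes (2 of 14 measured lower, 4 adjusted over the list alone, adjusted p = 0.0061, adjusted p = 0.34 with an estimated correlation), with Nr0b2 at -1.93 ± 0.37.

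In air, liver differed between ZT16-20 and ZT4-8 in 559 of 9451 genes, 306 higher and 253 lower in the dark phase. Arntl rose from 1.09 ± 0.18 to 21.6 ± 2.62 CPM (4.28 ± 0.25, adjusted p = 3.6e-10) and Cry1 by 3.00 ± 0.21. Dbp fell (-4.30 ± 0.39, adjusted p = 1.4e-05) and Nr1d1, a repressor of Arntl, changed by -4.08 ± 0.34. Cdkn1a (3.12 ± 0.22) rose, and Ccnd1 (-2.22 ± 0.43) and the lipid droplet gene Cidec (-3.37 ± 0.64) fell. Clock genes went both ways (4 higher and 5 lower of 16 measured, 4 and 5 adjusted over the list alone, adjusted p = 0.99, median -0.26, mean -0.36 and the set test upwards). Cholesterol synthesis genes were lower in the dark phase (4 of 20 measured lower, 10 adjusted over the list alone, adjusted p = 1.5e-05, adjusted p = 0.22 with an estimated correlation). So were fatty acid synthesis genes (1 higher and 3 lower of 18 measured, 1 and 5 adjusted over the list alone, adjusted p = 0.015, adjusted p = 0.72 with an estimated correlation), with Elovl6 at -1.46 ± 0.22. Glucocorticoid-induced genes were higher (4 of 17 measured higher, 8 higher and 3 lower adjusted over the list alone, adjusted p = 0.00039, adjusted p = 0.13 with an estimated correlation), with Tat at 1.28 ± 0.19. Gluconeogenesis and fasting genes were higher too (3 of 12 measured higher, 7 higher and 1 lower adjusted over the list alone, adjusted p = 6.9e-05, adjusted p = 0.13 with an estimated correlation), with Igfbp1 at 1.77 ± 0.36. Nuclear subunits of oxidative phosphorylation (OXPHOS) were higher as a list (2 of 46 measured higher, 13 adjusted over the list alone, adjusted p = 7.8e-06, adjusted p = 0.22 with an estimated correlation), with Cyc1 at 0.64 ± 0.13. Left out singly, ZT4-8 libraries A and D and ZT16-20 library C, all in air, gave 346, 352 and 364 called genes.

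**Figure D1:**
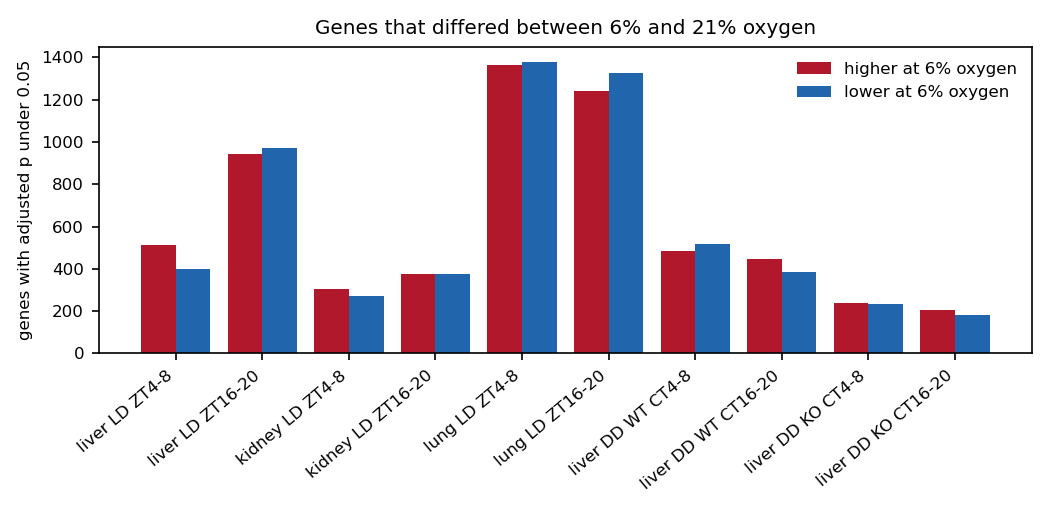
Bars side by side show the number of genes called higher (red) and lower (blue) at 6% against 21% oxygen. They cover each of the 10 comparisons of oxygen, from edgeR at an adjusted p under 0.05. Lung had the most, 2743 at ZT4-8 and 2568 at ZT16-20, and KO liver in darkness at CT16-20 the fewest, 384.

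In kidney at ZT4-8, Cdkn1a rose from 14.2 ± 3.14 to 177 ± 33.3 CPM (3.62 ± 0.18, adjusted p = 5.6e-11), the immediate early gene Egr1 by 3.26 ± 0.23, Ankrd37 by 3.64 ± 0.33 and Ddit4 by 3.30 ± 0.37. Rpph1, the RNA component of RNase P, rose by 5.34 ± 0.32. The growth factor gene Fgf18 (-2.76 ± 0.33), the endothelial transcription factor gene Sox18 (-2.76 ± 0.34), Clec2d (-2.26 ± 0.31), Grrp1 (-2.18 ± 0.26), Rhov (-2.02 ± 0.35) and the nuclear RNA Neat1 (-2.09 ± 0.12) fell. Of 10878 genes, 574 were called, 303 higher and 271 lower. Left out singly, the ZT4-8 air libraries B and C gave 342 and 1017, and a fit on only the libraries compared gave 264. The immediate early list rose (13 of 16 measured higher, 13 adjusted over the list alone, adjusted p = 2.2e-43), with Junb at 1.67 ± 0.14. Genes induced by glucocorticoids rose (9 of 16 measured higher, 11 adjusted over the list alone, adjusted p = 1.1e-26), with Cebpd at 4.71 ± 0.44. Other HIF targets rose (8 of 27 measured higher, 8 adjusted over the list alone, adjusted p = 4.7e-08), with Adm at 1.88 ± 0.33, and Vegfa was not called (-0.04 ± 0.10, adjusted p = 0.87). So did p53 targets (4 of 13 measured higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 2.5e-09), with Sesn1 at 1.43 ± 0.16. Glycolytic genes were higher (3 of 15 measured higher, 5 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation), with the lactate exporter gene Slc16a3 at 2.23 ± 0.42. Heat shock genes fell (6 of 17 measured lower, 8 adjusted over the list alone, adjusted p = 2.1e-06), with Hspa8 at -0.85 ± 0.14. Clock genes went both ways (7 higher and 6 lower of 17 measured, 7 and 8 adjusted over the list alone, adjusted p = 0.016, adjusted p = 0.051 with an estimated correlation, median -0.03, mean 0.42 and the set test upwards). Nr1d1 rose (1.91 ± 0.19), and Cry1 (-1.69 ± 0.28) and Dbp (-1.29 ± 0.15) fell. Among tubule transport genes (3 of 22 measured lower, 3 adjusted over the list alone, adjusted p = 0.42) the water channel gene Aqp1 fell (-0.50 ± 0.10).

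In kidney at ZT16-20, Ankrd37 (4.44 ± 0.33, adjusted p = 3.9e-08), Ddit4 (3.78 ± 0.39), Arrdc2 (3.47 ± 0.26), Cdkn1a (3.23 ± 0.17) and Maff (3.19 ± 0.27) rose. Sox18 (-2.42 ± 0.32), the DNA methyltransferase gene Dnmt3a (-2.01 ± 0.18), Frs3 (-1.85 ± 0.22) and Tyw3 (-1.83 ± 0.21) fell. Of 10878 genes, 751 were called, 374 higher and 377 lower. Immediate early genes rose (13 of 16 measured higher, 13 adjusted over the list alone, adjusted p = 2.1e-48). The glucocorticoid list rose (11 of 16 measured higher, 15 adjusted over the list alone, adjusted p = 3.5e-32), with Mt2 at 2.12 ± 0.16. The integrated stress response rose (4 of 14 measured higher, 6 adjusted over the list alone, adjusted p = 1.3e-05). Further HIF targets rose (7 of 27 measured higher, 9 adjusted over the list alone, adjusted p = 1.3e-07), as did p53 targets (3 higher and 1 lower of 13 measured, 4 and 1 adjusted over the list alone, adjusted p = 4.3e-07). Clock genes rose as a list (8 higher and 2 lower of 17 measured, 11 and 3 adjusted over the list alone, adjusted p = 9.0e-08), with Ciart at 4.39 ± 0.37 and Dbp at 1.09 ± 0.18. Among tubule transport genes (3 higher and 2 lower of 22 measured, 4 and 2 adjusted over the list alone, adjusted p = 0.90, median -0.02, mean 0.02 and the set test upwards), the collecting duct genes Aqp2 (1.01 ± 0.19) and Scnn1b (0.96 ± 0.21) were higher. Gapdh, a glycolytic gene with many pseudogenes and so uncertain, took either 3.64 to 9.27 or 187 to 317 CPM in single kidney libraries. All 4 libraries at ZT16-20 in air were high and all 4 at 6% low, and at ZT4-8 air D, 6% A and 6% D were high. The brown fat gene Ucp1 (-5.23 ± 1.22, adjusted p = 0.020) and the adipose list (1 higher and 2 lower of 10 measured, 1 and 8 adjusted over the list alone, adjusted p = 0.00033, adjusted p = 0.35 with an estimated correlation) were lower. The Gapdh call (-6.33 ± 1.65, adjusted p = 0.038) ended without any 1 of the 8 libraries, with log2 fold changes between -6.36 and -6.31 and an adjusted p up to 0.10. The Ucp1 call ended without air C or D or 6% A, C or D, and its log2 fold change stayed between -6.20 and -4.79, with an adjusted p up to 0.066.

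The oxygen response of kidney differed between the phases in 40 of 10878 genes, 25 higher and 15 lower in the dark phase. Dbp (2.38 ± 0.24, adjusted p = 2.7e-05), its relative Tef (1.17 ± 0.19), Susd3 (1.49 ± 0.20), the potassium channel gene Kcnk5 (1.23 ± 0.20) and Herpud1 (0.88 ± 0.15) had the higher response in the dark. Nfil3 (-2.38 ± 0.27), Clpx (-1.21 ± 0.18) and Ddc, of dopamine synthesis (-1.45 ± 0.24), had the lower one. Clock genes led the list tests (4 higher and 3 lower of 17 measured, 9 and 3 adjusted over the list alone, adjusted p = 0.0022). Without ZT4-8 air library C the count was 155, and without ZT4-8 6% library D or ZT16-20 air library D it was 25 or 23. DESeq2 called 88, and a replicate block gave 20. In air, 119 genes differed between the phases in kidney, 58 higher and 61 lower at ZT16-20. Arntl (3.42 ± 0.36, adjusted p = 2.0e-05), Nfil3 (3.33 ± 0.21), Cry1 (1.90 ± 0.20) and Ypel2 (1.82 ± 0.17) rose. Dbp (-4.29 ± 0.18, adjusted p = 1.8e-12), Nr1d1 (-3.80 ± 0.25), Nr1d2 (-2.55 ± 0.38) and Fgf18 (-1.97 ± 0.29) fell. Clock genes made up 11 of the calls (5 higher and 6 lower of 17 measured, 5 and 7 adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.15 with an estimated correlation). Left out singly, ZT4-8 air libraries B, C and D gave 66, 372 and 57 genes, and ZT16-20 air libraries A, C and D gave 65, 65 and 70. DESeq2 called 219, and a fit on only the libraries compared gave 50.

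In lung at ZT4-8, Apold1, an endothelial early response gene (mm10, chromosome 6, 134981718 to 134986836), rose from 0.861 ± 0.733 to 104 ± 24.5 CPM (6.88 ± 0.31, adjusted p = 3.1e-13). The AP-1 genes Fosl1 (4.99 ± 0.50) and Fosb (3.69 ± 0.34), Atf3 (4.01 ± 0.15), Mpp3 (4.14 ± 0.27) and Cebpd (3.62 ± 0.25) followed. Sox18 fell from 210.0 ± 27.2 to 16.3 ± 1.89 CPM (-3.69 ± 0.22, adjusted p = 2.8e-10). Of 12150 genes, 2743 were called, 1363 higher and 1380 lower. Immediate early genes rose throughout (17 of 17 measured higher, 17 adjusted over the list alone, adjusted p = 7.5e-46), with Klf4 at 1.91 ± 0.11. Other HIF targets rose (13 higher and 1 lower of 29 measured, 13 and 2 adjusted over the list alone, adjusted p = 3.8e-10), with the vasoconstrictor gene Edn1 at 3.62 ± 0.16. Genes induced by glucocorticoids rose (9 of 18 measured higher, 11 adjusted over the list alone, adjusted p = 8.6e-16), with Sgk1 at 2.02 ± 0.14. The integrated stress response rose (9 higher and 1 lower of 14 measured, 9 and 1 adjusted over the list alone, adjusted p = 1.3e-08), with Atf4 at 1.47 ± 0.13. So did p53 targets (8 of 14 measured higher, 8 adjusted over the list alone, adjusted p = 1.4e-08), with Plk2 at 1.71 ± 0.16. Cytokine and NF-kB genes rose (9 of 15 measured higher, 10 adjusted over the list alone, adjusted p = 1.6e-06), with Tnfaip3 at 2.10 ± 0.16. Glycolytic genes were higher (5 of 14 measured higher, 5 adjusted over the list alone, adjusted p = 0.0055, adjusted p = 0.34 with an estimated correlation), with Hk2 at 1.58 ± 0.20. Endothelial genes were higher (5 of 16 measured higher, 6 adjusted over the list alone, adjusted p = 0.0071, adjusted p = 0.24 with an estimated correlation), with the tight junction gene Cldn5 at 1.58 ± 0.12. Interferon-induced genes leaned lower (1 higher and 7 lower of 24 measured, 1 and 7 adjusted over the list alone, adjusted p = 0.060), with Oasl2 at -1.09 ± 0.23. Heat shock genes went both ways (5 higher and 8 lower of 16 measured, 5 and 8 adjusted over the list alone, adjusted p = 0.13), with Hsph1 at -1.32 ± 0.18. Among the largest falls by size were the muscle genes Myh8 (-9.54 ± 2.97), Acta1 (-8.63 ± 2.65), Tnnc2 (-7.68 ± 2.46) and Tnni2 (-4.55 ± 1.49) and the squamous keratin gene Krt13 (-8.47 ± 2.81). At ZT4-8, Myh8, Acta1 and Krt13 were highest in air libraries B and C. Without either library, each of these 5 calls ended, with log2 fold changes still between -8.99 and -3.88 and adjusted p between 0.057 and 0.24. Krt4, chosen after its values were seen, stood at 2795 and 165 CPM in ZT4-8 air libraries B and C and 918 in ZT16-20 air library D, against at most 21.8 in the other lung libraries. Without these 3 libraries, a setting chosen after seeing the data, 1872 genes were called at ZT4-8 and 2392 at ZT16-20. In that fit Myh8 (-5.01, adjusted p 0.00037), Acta1 (-3.97, 0.00059), Tnnc2 (-3.29, 0.00087) and Tnni2 (-0.80, 0.043) were called lower at ZT4-8, and Krt13 (-2.24, 0.44) was not. Only air libraries A and D were then left at ZT4-8. In the 5 other air libraries of both times, Acta1 reached at most 38.9 CPM and Tnnc2 at most 13.7.

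In lung at ZT16-20, Apold1 (6.49 ± 0.35, adjusted p = 4.1e-12), Fosl1 (5.76 ± 0.60), Atf3 (4.05 ± 0.15), Fosb (3.38 ± 0.34) and Csrnp1 (3.32 ± 0.18) rose. Sox18 (-3.45 ± 0.22, adjusted p = 9.3e-10), Rtp3 (-3.34 ± 0.25), Kctd21 (-2.64 ± 0.26), Grrp1 (-2.27 ± 0.21) and Calhm2 (-2.27 ± 0.27) fell. Of 12150 genes, 2568 were called, 1242 higher and 1326 lower. The immediate early list rose again (16 of 17 measured higher, 16 adjusted over the list alone, adjusted p = 9.2e-35), as did other HIF targets (15 higher and 3 lower of 29 measured, 16 and 3 adjusted over the list alone, adjusted p = 1.2e-09). Glucocorticoid-induced genes rose (11 of 18 measured higher, 13 adjusted over the list alone, adjusted p = 7.4e-18). The integrated stress response rose (9 of 14 measured higher, 9 adjusted over the list alone, adjusted p = 4.8e-08), as did p53 targets (6 of 14 measured higher, 7 higher and 1 lower adjusted over the list alone, adjusted p = 1.8e-05). Cholesterol synthesis genes rose (9 of 19 measured higher, 10 adjusted over the list alone, adjusted p = 0.00034), with Fdps at 0.91 ± 0.16. Fatty acid oxidation genes were lower (6 of 20 measured lower, 8 adjusted over the list alone, adjusted p = 0.0040, adjusted p = 0.31 with an estimated correlation), with the carnitine palmitoyltransferase gene Cpt1a at -0.80 ± 0.13. So were interferon-induced genes (1 higher and 7 lower of 24 measured, 1 and 8 adjusted over the list alone, adjusted p = 0.0023, adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes were slightly higher (10 of 47 measured higher, 11 adjusted over the list alone, adjusted p = 0.0023, adjusted p = 0.26 with an estimated correlation), with Rpl24 at 0.53 ± 0.10. Neutrophil markers were higher (7 of 11 measured higher, 8 adjusted over the list alone, adjusted p = 1.8e-05, adjusted p = 0.073 with an estimated correlation), with Retnlg at 2.15 ± 0.32 and S100a9 at 1.84 ± 0.38. Erythroid markers were lower (2 of 4 measured lower, 2 adjusted over the list alone, adjusted p = 0.025, adjusted p = 0.32 with an estimated correlation).

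The oxygen response of lung differed between the phases in 31 of 12150 genes, 17 higher and 14 lower in the dark phase. Rasl11a (-1.63 ± 0.16, adjusted p = 7.1e-06), Arntl (-3.09 ± 0.37), Spon2 (-3.18 ± 0.42) and Nfil3 (-1.81 ± 0.27) had the lower response in the dark. Dbp (2.68 ± 0.27, adjusted p = 1.2e-05), its relative Hlf (1.99 ± 0.29), Tspan4 (1.70 ± 0.21) and Cys1 (1.47 ± 0.19) had the higher one. Clock genes passed the set test (5 higher and 3 lower of 17 measured, 7 and 3 adjusted over the list alone, adjusted p = 0.00013, adjusted p = 0.064 with an estimated correlation). So did cholesterol synthesis genes (1 of 19 measured higher, 1 adjusted over the list alone, adjusted p = 0.00018), with Fdps at 1.29 ± 0.22. Neutrophil markers, without a call over all genes, leaned to a higher response in the dark (no call among 11 measured, 4 higher and 0 lower adjusted over the list alone, adjusted p = 2.2e-07, adjusted p = 0.064 with an estimated correlation). Without ZT4-8 6% library D the count was 19, and DESeq2 called 66. In air, 119 genes differed between the phases, 42 higher and 77 lower at ZT16-20. Arntl (3.06 ± 0.27, adjusted p = 1.8e-07), Nfil3 (2.02 ± 0.21) and Rasl11a (1.94 ± 0.12) rose. Nr1d1 (-5.61 ± 0.19, adjusted p = 3.3e-16), Dbp (-4.49 ± 0.21), Ifitm6 (-2.14 ± 0.28) and Retnlg (-2.40 ± 0.32) fell. Neutrophil markers fell together (6 of 11 measured lower, 7 adjusted over the list alone, adjusted p = 2.0e-15), with Cxcr2 at -1.62 ± 0.30. Clock genes went both ways (5 higher and 6 lower of 17 measured, 5 and 9 adjusted over the list alone, adjusted p = 8.0e-08). Cholesterol synthesis genes were lower as a list (1 of 19 measured lower, 2 adjusted over the list alone, adjusted p = 0.0012), with Fdps at -0.82 ± 0.16. Left out singly, ZT4-8 air libraries B and C gave 75 and 78 genes, a fit on only the libraries compared gave 77 and DESeq2 called 212. Without these and ZT16-20 air library D together 29 genes were called and 19 for the oxygen response.

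**Figure D2:**
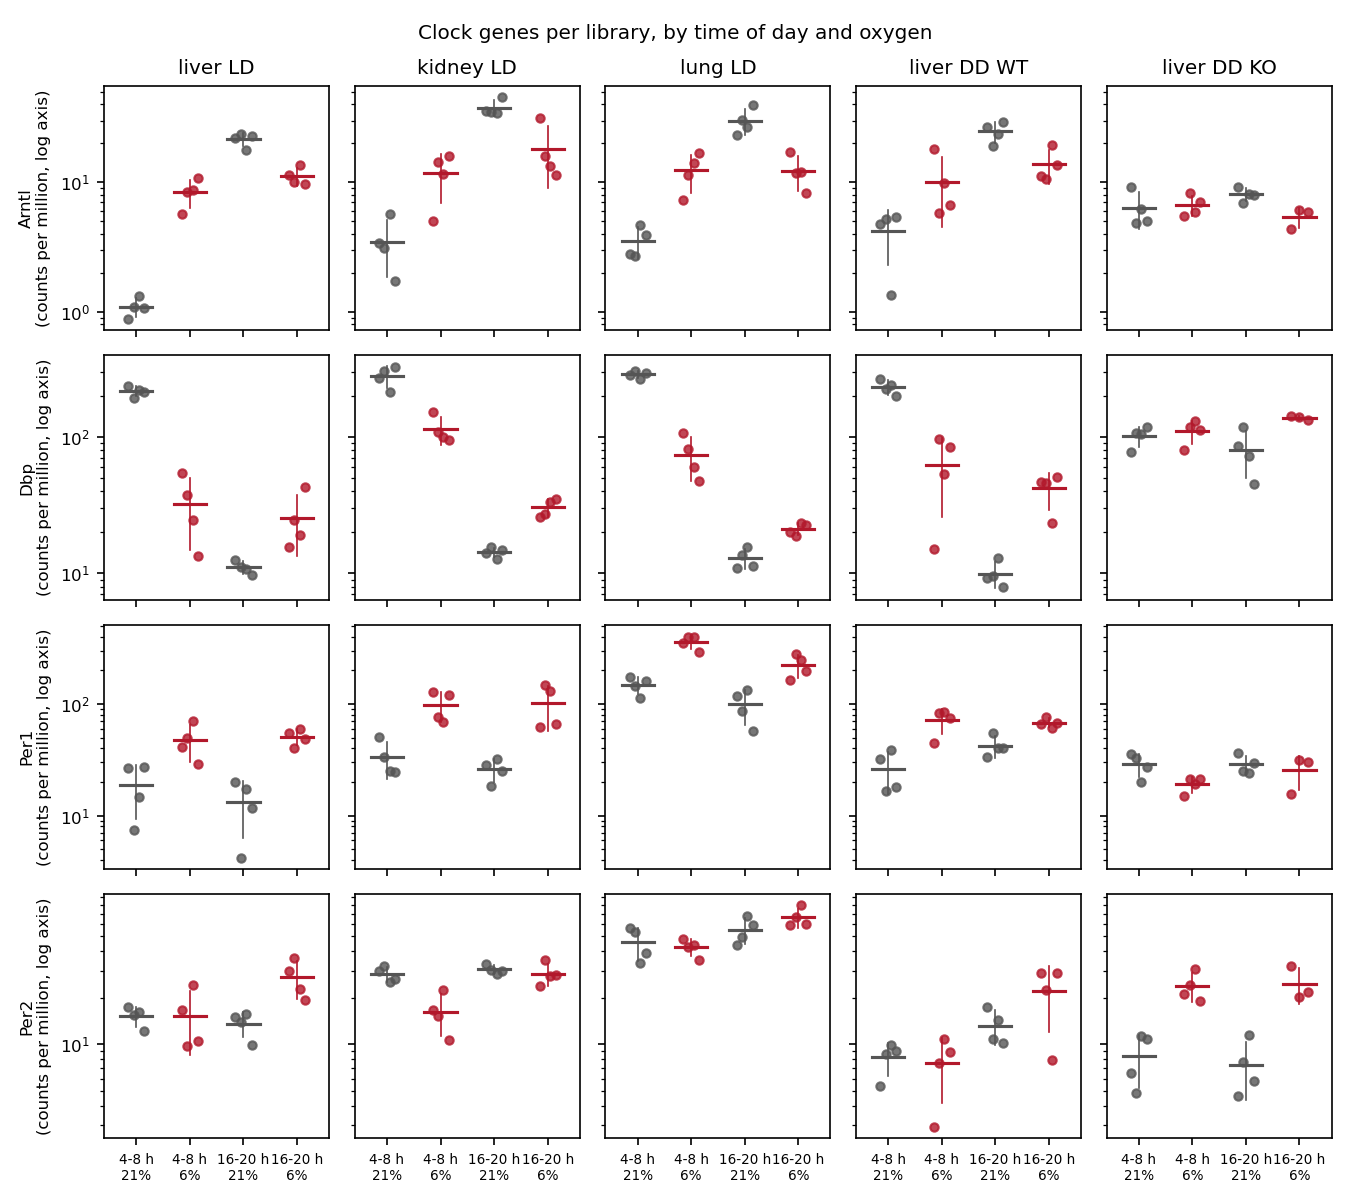
CPM of Arntl, Dbp, Per1 and Per2 on a log axis in single libraries (points), with the group mean (line) and SD (bar), in air (grey) and 6% oxygen (red) at each time in the 5 sets of libraries. In liver in LD, Arntl moved from 1.09 to 8.39 at ZT4-8 and from 21.6 to 11.2 at ZT16-20, and in libraries labelled KO it stood between 5.40 and 8.07 in all 4 groups.

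The next question was whether the tissues differed in their response, tested over both phases with a term for each mouse on 10649 genes. Libraries of the same time, oxygen level and replicate letter were taken to come from 1 mouse. Here higher means a higher log2 fold change at 6% oxygen in the tissue named first. Liver and kidney differed in 685 genes, liver and lung in 1619 and kidney and lung in 857. The response of Cited2, a feedback inhibitor of HIF, was higher in liver than in kidney (3.15 ± 0.15, adjusted p = 1.1e-18) and than in lung (3.67 ± 0.15, adjusted p = 3.5e-21). So were those of Hilpda (4.02 ± 0.23 and 3.91 ± 0.18), the ephrin gene Efna1 (3.01 ± 0.20 and 5.16 ± 0.20) and Vegfa (1.54 ± 0.13 and 1.17 ± 0.13). Against kidney, other HIF targets had the higher response in liver (9 higher and 1 lower of 29 measured, 11 and 2 adjusted over the list alone, adjusted p = 1.3e-15). So did gluconeogenesis and fasting genes (6 of 11 measured higher, 6 adjusted over the list alone, adjusted p = 1.0e-09), with Igfbp1 at 4.09 ± 0.30. Immediate early genes had the higher response in liver (7 higher and 1 lower of 17 measured, 8 and 1 adjusted over the list alone, adjusted p = 1.3e-07), as did the integrated stress response (3 of 12 measured higher, 4 adjusted over the list alone, adjusted p = 6.1e-05), with Gdf15 at 3.91 ± 0.25. The amino acid transporter gene Slc38a2 (2.54 ± 0.14), Klhl25 (3.22 ± 0.21) and Tgm2 (2.07 ± 0.14) did so too.

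Against lung, other HIF targets again had the higher response in liver (10 higher and 3 lower of 29 measured, 14 and 4 adjusted over the list alone, adjusted p = 1.6e-12), with Gadd45b, outside that list, at 4.40 ± 0.24 and Btg2 at 3.14 ± 0.20. Immediate early genes did so as well (8 higher and 3 lower of 17 measured, 9 and 3 adjusted over the list alone, adjusted p = 6.9e-06, adjusted p = 0.086 with an estimated correlation). Atf4 (-1.01 ± 0.13), Hspa1b (-2.63 ± 0.33) and Mir22hg (-2.13 ± 0.14) had the higher response in lung. OXPHOS subunits had the lower response in liver (9 of 46 measured lower, 11 adjusted over the list alone, adjusted p = 0.0011, adjusted p = 0.50 with an estimated correlation), with Cox4i1 at -0.53 ± 0.13. Ribosomal proteins did not pass the set test (6 of 47 measured lower, 5 adjusted over the list alone, adjusted p = 0.056), with Rpl24 at -0.43 ± 0.12. Between kidney and lung, the calcineurin regulator gene Rcan1 (-2.69 ± 0.16, adjusted p = 1.7e-15), Ctgf (-2.68 ± 0.19), the tissue factor gene F3 (-2.18 ± 0.17), Errfi1 (-2.32 ± 0.18), Ackr3 (-2.23 ± 0.18), Dusp6 (-2.56 ± 0.21), Plat (-1.42 ± 0.13) and Edn1 (-2.39 ± 0.26) had the higher response in lung. Ciart (2.57 ± 0.26) and Btg2 (1.28 ± 0.20) had the higher response in kidney. The integrated stress response had the higher response in lung (4 of 12 measured lower, 5 adjusted over the list alone, adjusted p = 0.0080, adjusted p = 0.32 with an estimated correlation). So did OXPHOS subunits (6 of 46 measured lower, 7 adjusted over the list alone, adjusted p = 0.00060, adjusted p = 0.66 with an estimated correlation) and ribosomal proteins (3 of 47 measured lower, 8 adjusted over the list alone, adjusted p = 0.022, adjusted p = 0.64 with an estimated correlation). The hepatocyte gene Apoh, which neither kidney nor lung is known to make in quantity, differed in both comparisons with lung (3.45 ± 0.56 and 3.75 ± 0.57). Without the 3 mice whose lung libraries held squamous transcripts, liver and lung differed in 1248 genes and kidney and lung in 488.

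Across the 6 LD comparisons of oxygen, 53 genes rose and 26 fell in every one, of 8617 tested in all. With darkness included, 29 rose and 4 fell in all 10 comparisons, of 7617. Those that rose included Ankrd37, with log2 fold changes from 2.97 to 4.53, and Atf3, from 2.92 to 5.63. Others were the immediate early genes Jun, Klf4, Nr4a1 and Ier3, the HIF targets Ddit4, Hilpda and Slc2a1, and the cold-inducible RNA-binding gene Cirbp. Il16, the splicing regulators Rbm5 and Rsrp1, and Sox18 fell. Early and late comparisons of 1 tissue shared 289 rises and 226 falls in LD liver, against 51.2 and 40.9 by chance, with 34 genes called in opposite directions. In kidney they shared 156 and 125 against 10.4 and 9.39, with 9 in opposite directions.

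**Figure D3:**
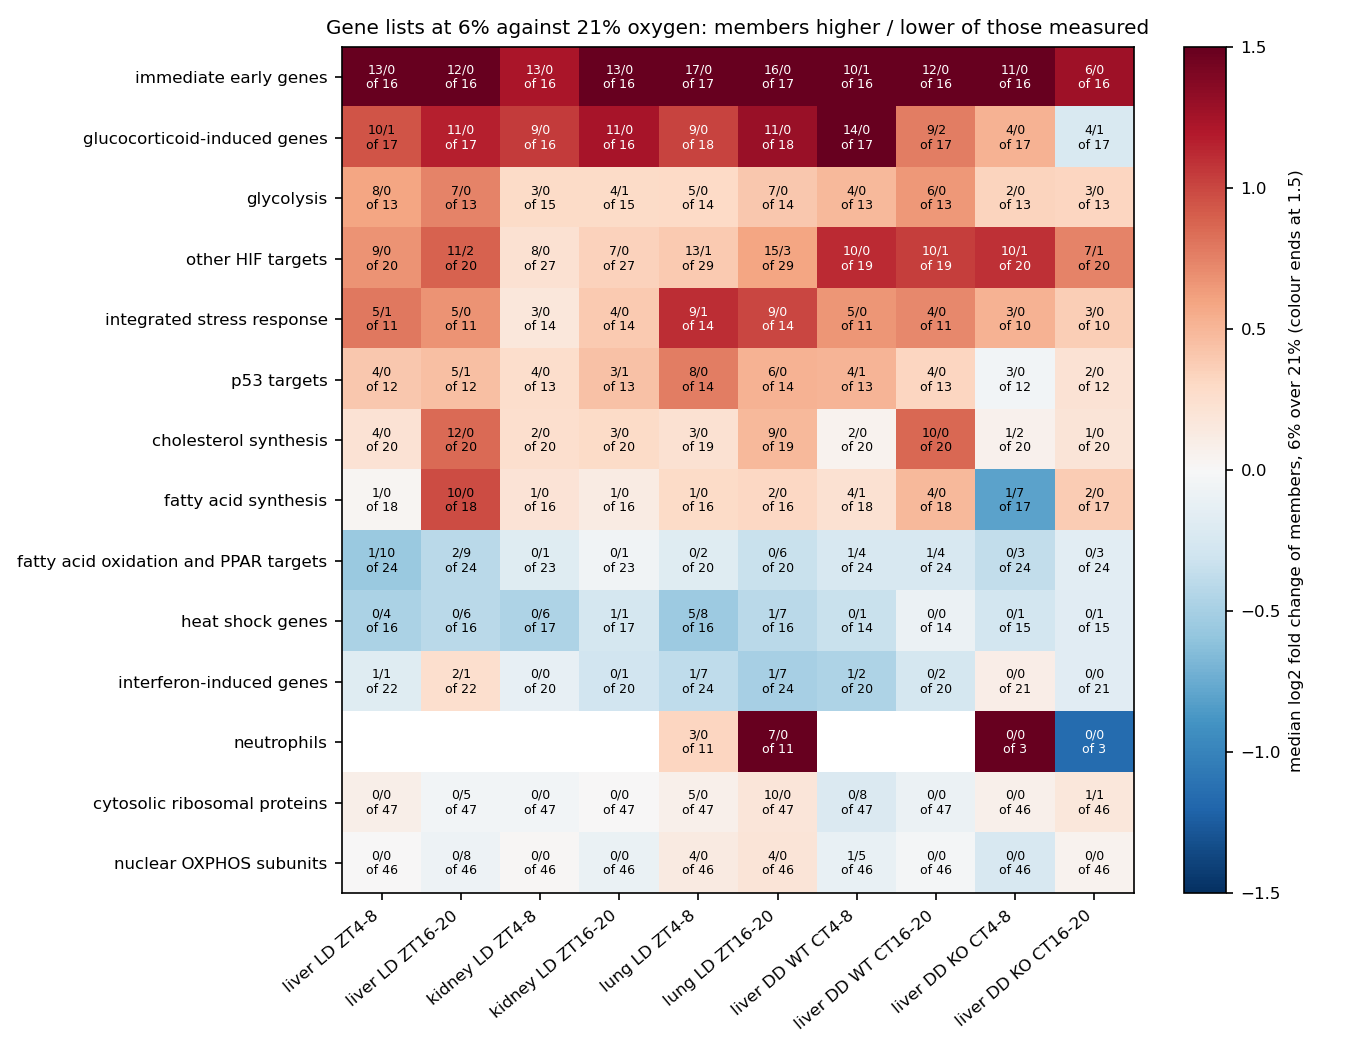
Numbers of list members called higher or lower, of those measured, for each gene list and each of the 10 comparisons of oxygen. The colour scale shows the median log2 fold change and ends at ±1.5, with blank cells where fewer than 3 members were tested. Immediate early genes were higher in 13 of 16 measured members in liver at ZT4-8 and in kidney at both times, and in 17 of 17 in lung at ZT4-8.

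The experiment in constant darkness asked whether the response depends on a working clock. In WT liver at CT4-8, Igfbp1, which binds insulin-like growth factors, rose (5.28 ± 0.30, adjusted p = 4.8e-10). So did Gdf15 (4.51 ± 0.25), Ddit4 (4.37 ± 0.52), the metallothionein gene Mt2 (4.65 ± 0.45) and the centromere gene Cenpu (5.36 ± 0.87). The growth hormone target Cish (-3.22 ± 0.47, adjusted p = 0.00027), Foxq1 (-3.01 ± 0.33), Inhbe (-2.67 ± 0.34), Rnf43 (-2.58 ± 0.36) and Hhex (-2.39 ± 0.29) fell. Of 8507 genes, 1001 were called, 485 higher and 516 lower, and 615 without 6% library C. A fit on only the libraries compared gave 526, 321 higher and 205 lower, and no filter on low counts gave 535 and 458. Air library A differed most from its group mean of all 79 libraries, with an SD over genes of 0.63 in log2(CPM + 1) against at most 0.43, and without it 999 genes were called. Genes induced by glucocorticoids rose (14 of 17 measured higher, 15 adjusted over the list alone, adjusted p = 2.2e-40), with Cdkn1a at 3.99 ± 0.21 and Tat at 2.65 ± 0.17. Further HIF targets rose (10 of 19 measured higher, 12 adjusted over the list alone, adjusted p = 2.0e-17), with Vegfa at 1.01 ± 0.16. Immediate early genes rose (10 higher and 1 lower of 16 measured, 11 and 1 adjusted over the list alone, adjusted p = 1.5e-17), with Klf4 at 3.94 ± 0.34. So did gluconeogenesis and fasting genes (8 of 12 measured higher, 8 adjusted over the list alone, adjusted p = 5.3e-12) and p53 targets (4 higher and 1 lower of 13 measured, 5 and 1 adjusted over the list alone, adjusted p = 3.9e-07). Glycolytic genes were higher (4 of 13 measured higher, 5 adjusted over the list alone, adjusted p = 0.00070, adjusted p = 0.13 with an estimated correlation), with Pfkfb3 at 2.90 ± 0.57. So was the integrated stress response (5 of 11 measured higher, 7 adjusted over the list alone, adjusted p = 0.00026, adjusted p = 0.086 with an estimated correlation). Clock genes went both ways (6 higher and 2 lower of 15 measured, 6 and 4 adjusted over the list alone, adjusted p = 0.32, median -0.08, mean 0.20 and the set test upwards). Per1 rose (1.48 ± 0.24) and Dbp fell (-1.88 ± 0.36). With the LD liver at ZT4-8, WT liver shared 205 rises and 110 falls, against 27.9 and 22.4 by chance. In opposite directions 7 genes were called.

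In WT liver at CT16-20, Cenpu (5.36 ± 0.80, adjusted p = 0.00038), Hilpda (4.82 ± 0.30), Atf3 (4.59 ± 0.56), Gdf15 (4.40 ± 0.24) and Ankrd37 (4.07 ± 0.50) rose. Rsrp1 (-2.56 ± 0.16, adjusted p = 4.2e-10), Foxa2 (-2.51 ± 0.24), Foxq1 (-2.10 ± 0.36) and Mettl20 (-1.92 ± 0.37) fell. Of 8507 genes, 836 were called, 449 higher and 387 lower. Other HIF targets rose (10 higher and 1 lower of 19 measured, 13 and 1 adjusted over the list alone, adjusted p = 3.7e-17), with Egln3, an oxygen sensor of the pathway, at 1.58 ± 0.19. The glucocorticoid list rose (9 higher and 2 lower of 17 measured, 10 and 3 adjusted over the list alone, adjusted p = 1.2e-06), with Sgk1 at 1.59 ± 0.16 but Tsc22d3 at -1.30 ± 0.17. Immediate early genes rose (12 of 16 measured higher, 14 adjusted over the list alone, adjusted p = 4.0e-24). Glycolytic genes were higher (6 of 13 measured higher, 8 adjusted over the list alone, adjusted p = 3.6e-05), with Tpi1 at 0.62 ± 0.15. Cholesterol synthesis genes were higher (10 of 20 measured higher, 12 adjusted over the list alone, adjusted p = 1.2e-10), with Insig1 at 1.69 ± 0.24. Fatty acid oxidation genes were lower as a list (1 higher and 4 lower of 24 measured, 1 and 6 adjusted over the list alone, adjusted p = 0.0026, adjusted p = 0.20 with an estimated correlation). Clock genes were higher as a list (6 higher and 1 lower of 15 measured, 9 and 2 adjusted over the list alone, adjusted p = 0.00073, adjusted p = 0.11 with an estimated correlation), with Ciart at 2.93 ± 0.35 and Dbp at 2.05 ± 0.43. Cry1 fell (-1.03 ± 0.25). With the LD liver at ZT16-20 they shared 325 rises and 252 falls, against 48.2 and 40.4 by chance.

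In WT liver in darkness the response differed between the times in 138 of 8507 genes, 70 higher and 68 lower at CT16-20. Cdkn1a (-3.23 ± 0.27, adjusted p = 4.3e-07), Tat (-2.12 ± 0.23), Igfbp1 (-2.56 ± 0.37), the lipid droplet gene Plin5 (-1.77 ± 0.22), the glycogen-targeting genes Ppp1r3c (-2.63 ± 0.34) and Ppp1r3b (-1.74 ± 0.25) and Slc45a3 (-2.17 ± 0.25) had the lower response at CT16-20. Dbp (3.94 ± 0.56, adjusted p = 0.0023) and Fam20c (1.62 ± 0.24) had the higher one. Glucocorticoid-induced genes had the lower response as a list (7 of 17 measured lower, 9 adjusted over the list alone, adjusted p = 6.6e-22), with Fkbp5 at -1.45 ± 0.25. Left out singly, CT4-8 6% libraries B, C and D, CT16-20 air library B and CT16-20 6% libraries A and D gave 85, 73, 73, 68, 73 and 74 genes. In air, 311 genes differed between the times, 153 higher and 158 lower at CT16-20. Cdkn1a (3.05 ± 0.21, adjusted p = 3.2e-09), Fam222a (2.79 ± 0.31), Igfbp1 (2.74 ± 0.27) and Arntl (2.53 ± 0.34) were higher. Dbp (-4.52 ± 0.43, adjusted p = 9.7e-06), Nr1d1 (-4.30 ± 0.25) and Rnf43 (-1.80 ± 0.32) were lower. Genes induced by glucocorticoids were higher (10 of 17 measured higher, 10 adjusted over the list alone, adjusted p = 6.5e-24), with Tat at 2.10 ± 0.17. Left out singly, CT16-20 air libraries A, B and D gave 199, 175 and 189, and a fit on only the libraries compared gave 123, 68 higher and 55 lower. Without CT4-8 air library A the counts were 341 for time and 197 for the oxygen response.

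In libraries labelled KO at CT4-8, Atf3 (5.43 ± 0.96, adjusted p = 0.0072), Hilpda (4.56 ± 0.26), Gadd45a (4.46 ± 0.62) and Gdf15 (4.23 ± 0.36) rose. Fabp5 (-2.58 ± 0.51), Clec2d (-2.47 ± 0.29), Rsrp1 (-2.42 ± 0.18), Foxa2 (-2.01 ± 0.28) and the acetyl-CoA synthetase gene Acss2 (-1.97 ± 0.30) fell. Of 8520 genes, 476 were called, 241 higher and 235 lower. Without air library A or B or 6% library C the counts were 313, 314 and 287. Further HIF targets rose (10 higher and 1 lower of 20 measured, 11 and 1 adjusted over the list alone, adjusted p = 4.3e-19), with Vegfa at 1.20 ± 0.15. The immediate early list rose (11 of 16 measured higher, 13 adjusted over the list alone, adjusted p = 4.2e-27), with Klf2 at 1.79 ± 0.19. Fatty acid synthesis genes were lower (1 higher and 7 lower of 17 measured, 2 and 10 adjusted over the list alone, adjusted p = 1.5e-05, adjusted p = 0.24 with an estimated correlation), with Fads2 at -1.28 ± 0.27. Srebf1 rose (2.65 ± 0.24). Per2 rose (1.51 ± 0.28) and Per1 did not pass the test (-0.60 ± 0.23, adjusted p = 0.15). At CT16-20 (n = 3 at 6%), Hilpda (4.58 ± 0.27, adjusted p = 1.5e-09), Ier3 (4.56 ± 0.56) and Ankrd37 (4.30 ± 0.66) rose. Cyp4a31 (-3.23 ± 0.52), Foxq1 (-2.43 ± 0.41), Rsrp1 (-2.29 ± 0.19), Clec2d (-1.90 ± 0.31) and N4bp2l1 (-1.82 ± 0.29) fell. Of 8520 genes, 384 were called, 204 higher and 180 lower. Without air library B or 6% library A, B or C the counts were 230, 167, 180 and 229, and a replicate block gave 242. Other HIF targets rose (7 higher and 1 lower of 20 measured, 10 and 1 adjusted over the list alone, adjusted p = 8.7e-20). Immediate early genes were higher (6 of 16 measured higher, 9 adjusted over the list alone, adjusted p = 3.5e-13, adjusted p = 0.088 with an estimated correlation). Per2 rose again (1.72 ± 0.30).

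Between the times, the response of KO liver differed in 1 gene by edgeR, Cyp7a1 (4.26 ± 0.51, adjusted p = 0.0043). It stood at 63.0 ± 24.7 and 25.9 ± 9.06 CPM in air and 6% oxygen at CT4-8 and at 9.22 ± 3.10 and 72.5 ± 23.5 at CT16-20. DESeq2 called 24 genes, 657 genes had an unadjusted p under 0.05. Leaving out CT4-8 6% library B gave 13, and leaving out air library C of either time gave 2. In air, 2 genes differed between the times, Cyp7a1 (-2.77 ± 0.39, adjusted p = 0.026) and Gstm1 (-1.09 ± 0.18, adjusted p = 0.034). DESeq2 called 33, a fit on only the libraries compared gave 9, and 695 had an unadjusted p under 0.05. By edgeR the count was 1 without CT4-8 air library B or CT16-20 air library A and 0 without any other single library of the 8. Dbp (-0.35 ± 0.22, adjusted p = 0.71), Nr1d1 (-0.80 ± 0.36, adjusted p = 0.60), Arntl (0.34 ± 0.28, adjusted p = 0.82) and Cry1 (0.33 ± 0.34, adjusted p = 0.85) did not pass the test.

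The response was compared between the genotypes as the log2 fold change at 6% oxygen in KO minus that in WT liver. With separate tables, preparation is not separable from genotype in air, nor here if its effect differed by oxygen level. At CT4-8, 218 of 9011 genes differed, 104 higher and 114 lower in KO. Tns1 (-1.99 ± 0.23, adjusted p = 4.8e-06), Tat (-2.67 ± 0.39), Pdk4 (-4.44 ± 0.66), Igfbp3 (-1.72 ± 0.27), Susd6 (-1.47 ± 0.24) and Cdc42ep5 (-3.08 ± 0.53) had the lower response in KO. Fam20c (1.56 ± 0.25) and the xenobiotic receptor gene Nr1i3 (1.81 ± 0.29) had the higher one. Tat stood at 1046 ± 263 CPM in air and 6632 ± 548 at 6% oxygen in WT, and at 4458 ± 2666 and 4443 ± 629 in KO. Per1 (-2.08 ± 0.36, adjusted p = 0.0012) and Dbp (1.99 ± 0.45, adjusted p = 0.015) differed in opposite senses. Genes induced by glucocorticoids had the lower response in KO as a list (5 of 17 measured lower, 1 higher and 9 lower adjusted over the list alone, adjusted p = 9.2e-10), with Zbtb16 at -2.19 ± 0.43. Fatty acid synthesis genes were lower too (1 higher and 2 lower of 18 measured, 1 and 5 adjusted over the list alone, adjusted p = 5.4e-05, adjusted p = 0.46 with an estimated correlation), with Elovl5 at -2.06 ± 0.45 and Acly at -1.57 ± 0.37. So were fatty acid oxidation genes (3 of 24 measured lower, 3 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.46 with an estimated correlation). Left out singly, WT 6% libraries C and D, KO air library A and KO 6% libraries A and B gave 131, 136, 121, 119 and 339. A fit on only the libraries compared gave 126, 45 higher and 81 lower in KO. At CT16-20, 4 genes differed, Gnat1 (-2.79 ± 0.41, adjusted p = 0.00049), Mapk15 (2.26 ± 0.38, adjusted p = 0.0037), Nfil3 (1.59 ± 0.29, adjusted p = 0.012) and Mcm3 (-1.68 ± 0.32, adjusted p = 0.015). Nfil3 lost its call without WT air library C or KO 6% library A, and Mcm3 without WT air library B or C or KO 6% library B. Over all libraries left out singly their log2 fold changes stayed between 1.34 and 1.82 and between -1.79 and -1.54, with adjusted p up to 0.13 and 0.14. DESeq2 called 36, and a replicate block and a fit on only the libraries compared gave 7 each. The edgeR count was 2 without WT air library C, 8 without WT 6% library A and 10 without KO air library A or KO 6% library C. WT and KO liver shared 131 rises and 53 falls at CT4-8, against 13.5 and 13.8 by chance, with 11 genes called in opposite directions. At CT16-20 they shared 122 and 86, against 10.5 and 7.89, with 1.

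In air at CT4-8, KO and WT liver differed in 406 of 9011 genes, 204 higher and 202 lower in KO. Rnf167 (1.25 ± 0.15, adjusted p = 1.8e-06), the glycogen gene Ppp1r3g (4.30 ± 0.51), Mir682 (1.48 ± 0.20), Tat (2.09 ± 0.28), Igfbp1 (3.09 ± 0.39) and Acsl4 (1.93 ± 0.28) were higher. Etnk2 (-1.56 ± 0.22) and the coagulation factor gene F11 (-1.49 ± 0.21) were lower. Glucocorticoid-induced genes were higher (6 of 17 measured higher, 8 adjusted over the list alone, adjusted p = 7.3e-09, adjusted p = 0.12 with an estimated correlation). Gluconeogenesis and fasting genes were higher (2 of 12 measured higher, 4 adjusted over the list alone, adjusted p = 9.8e-05, adjusted p = 0.12 with an estimated correlation), and Pdk4 stood at 3.61 ± 0.52. Cholesterol synthesis genes were higher (4 of 20 measured higher, 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0082, adjusted p = 0.51 with an estimated correlation), with Fdps at 1.02 ± 0.21. Without KO air library A or C the counts were 228 and 246, and without WT air library A 321. With only the libraries compared fitted, 96 genes were called, 66 higher and 30 lower in KO, and 86 of them were among the 406. At CT16-20, 180 genes differed, 87 higher and 93 lower in KO. Dbp (3.00 ± 0.38, adjusted p = 3.2e-05), Nr1d1 (2.84 ± 0.38), Ciart (2.75 ± 0.44), Rnf167 (1.40 ± 0.15), Rogdi (1.31 ± 0.20) and the B cell chemokine gene Cxcl13 (2.47 ± 0.40) were higher. Cry1 (-1.71 ± 0.29, adjusted p = 0.00056), Arntl (-1.59 ± 0.29), Mapk15 (-1.80 ± 0.27) and the glutathione transferase gene Gstm1 (-1.39 ± 0.17) were lower. Heat shock genes were lower as a list (1 of 15 measured lower, 6 adjusted over the list alone, adjusted p = 8.9e-08), with Hspb1 at -2.42 ± 0.40. Fatty acid synthesis genes were lower (3 of 18 measured lower, 3 adjusted over the list alone, adjusted p = 9.5e-08, adjusted p = 0.17 with an estimated correlation), with Me1 at -2.40 ± 0.41. Acute phase genes were higher (7 of 21 measured higher, 16 adjusted over the list alone, adjusted p = 6.6e-13, adjusted p = 0.17 with an estimated correlation). Without WT air library A, C or D, or KO air library B or C, the count fell to between 78 and 113.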

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

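The test of blood cell lists behind the neutrophil pattern, the reading of the genotype difference itself, the thinned counts, the fits without 3 lung libraries, the comparison of these with the other air libraries and the second marker list were chosen only after the data were seen.

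Single libraries stood far from the other 3 of their group in 10 of 141 groups of values examined, by a gap rule that chance meets in about 1 in 20 groups. The WT liver library CT16-20 6% D in constant darkness held 2.03 M counts. Arntl stood at 45.5 CPM in kidney ZT16-20 air library D and at 1.35 CPM in WT constant-dark CT4-8 air library C. Foxa2 stood at 13.8 CPM in light-dark liver ZT4-8 6% library B. Acot3 stood at 9.25 CPM in light-dark liver ZT4-8 air library C and at 4.30 CPM in ZT16-20 air library A. Gapdh stood at 187 CPM in kidney ZT4-8 air library D. Apold1 stood at 67.5 CPM in lung ZT4-8 6% library B. Myh8 stood at 353 CPM in lung ZT16-20 air library D and at 1.82 CPM in lung ZT16-20 6% library A.

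The response to 6% oxygen differed between groups by the interaction test in 195 genes between times in light-dark liver, 40 in kidney, 31 in lung, 138 in WT and 1 in KO constant-dark liver. It differed between genotypes in 218 genes at CT4-8 and 4 at CT16-20, and between tissues in 685 genes for liver and kidney, 1619 for liver and lung and 857 for kidney and lung.

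Other splits of the same libraries into groups of the same sizes were fitted alike. For each plain comparison of groups there were 35 splits, and only the real split, 1 of 35, gave as many called genes. That is the smallest share 35 splits can reach, and it was not adjusted over the comparisons. It argues against chance for a comparison taken alone, but does not exclude it for each. The real count and the highest of the other splits were 911 and 0 for oxygen in light-dark liver at ZT4-8, 1915 and 3 at ZT16-20, and 559 and 2 for time. They were 574 and 14, 751 and 1, and 119 and 0 in kidney, and 2743 and 0, 2568 and 2, and 119 and 26 in lung. In constant darkness they were 1001 and 8, 836 and 3, and 311 and 11 in WT, and 476 and 1, 384 and 24, and 2 and 0 in KO. The 2 genes against 0 for time in KO liver leave chance open. Between genotypes in air they were 406 and 27 at CT4-8 and 180 and 4 at CT16-20. For the differences of responses between times and genotypes, 100 splits were drawn. Only the real one, 1 of 100, gave as many genes in light-dark liver (195 against 75), kidney (40 against 11) and lung (31 against 27). The same held between genotypes at CT4-8 (218 against 156). In WT constant-dark liver (138 against 138) and between genotypes at CT16-20 (4 against 6), 2 of 100 did so. These splits exchanged times or genotypes within an oxygen level, which also removes the plain difference between times or genotypes. They can argue against no difference of any kind, but cannot show that the responses to oxygen differed. For the difference between times in KO liver, 5 of 100 gave as many (1 against 9), and chance cannot be excluded. For tissues, only the real split, 1 of 23, gave as many, with 685 against 2, 1619 against 526 and 857 against 1. These splits exchanged oxygen levels between mice of a time, which also removes the oxygen response itself. They therefore cannot show that the tissues differed in their responses.

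The responses of WT and KO liver differed in more genes at CT4-8 than at CT16-20. That 1 WT control library stands apart is argued against, since leaving out CT4-8 air library A, the farthest from its group mean of all 79 libraries, gave 183 genes and leaving out library C, which stood apart in Arntl, gave 228, while WT 6% libraries C and D, KO air library A and KO 6% libraries A and B moved the count to 131, 136, 121, 119 and 339. Library depth is argued against as well, since counts thinned to 1 depth gave 181 at CT4-8 and 3 at CT16-20. A difference in the response between the genotypes remains a candidate explanation for the 218 genes. An equal preparation shift at both oxygen levels would cancel, but an unequal shift stays open.

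In 3 lung air libraries, ZT4-8 B and C and ZT16-20 D, transcripts of keratinised epithelium and skeletal muscle were high. Krt4 stood at 2795, 165 and 918 CPM there and at most at 21.8 elsewhere, and Acta1 at 1123, 1224 and 1172 CPM. On a second marker list of 30 genes, written before its values were looked up, 19 of 22 measured markers were highest in ZT4-8 B or ZT16-20 D, 2 of 16 libraries, where 12.5% would be by chance, and 10 of the 22 reached 10 CPM on average in the other 14 libraries too. Pieces of squamous epithelium in the lung sample are a candidate source. In 6 of 6 called list members, all 5 other air libraries lay below these 3, with Acta1 at most at 38.9 CPM. The 3 were picked for high values, so this cannot test oxygen as the reason. A change of lung cells at 6% oxygen stays open for the difference without them. Of these 6 genes, Acta1 and Tnnc2, 2 of 4 testable without the 3 libraries, stayed called, as did Myh8 and Tnni2, outside the 6. Ckm and Krt13 did not, and Krtdap and Lce3b had no test.

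Neutrophil markers were higher in lung at 6% oxygen at ZT16-20, with a median log2 fold change of 1.74. In air, 6 of 11 measured markers were called lower at ZT16-20 than at ZT4-8. More blood in the 6% libraries is argued against by the erythroid markers, whose median of -0.80 was the lower of the erythroid and lymphocyte medians, with lymphocytes at 0.42. That 1 library stands apart is argued against, since at most 1 of 7 called markers was lost without any 1 library. Low values in several air libraries together at ZT16-20 stay open, since the fall in air goes with them. More neutrophils in lung vessels, or more transcript per cell, may remain, as hypotheses that were not tested.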

How the results depend on the processing

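The fits without 3 lung control libraries or their mice, and the thinned counts, were chosen only after the data were seen, and the other alternatives were planned.

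Over the 27 comparisons, RLE scaling and no filter on low counts kept every count of called genes within 1.5 times, and RLE moved the median of all genes by at most 0.025. DESeq2 called more genes in all 27 and stayed within 1.5 times in 19. The other 8 were the difference between times in light-dark liver (299), kidney (88), lung (66) and KO liver (24), time in air in kidney (219), lung (212) and KO liver (33), and the genotype difference in response at CT16-20 (36). Fits on only the libraries compared were within 1.5 times in 10 of 19 and gave 264 genes for kidney at ZT4-8, 526 for WT liver at CT4-8, 50 and 77 for time in kidney and lung, 123 and 9 for time in WT and KO liver in darkness, 126 and 7 for the genotype difference in response at CT4-8 and CT16-20, and 96 for genotype in air at CT4-8. Of these 9, 2 were higher, KO time and the genotype difference at CT16-20, and 7 lower, and the cause was not tested. For the differences between times this fit is the one reported, so it gave no separate value. Where DESeq2 or the replicate block moved a count, the cause was not tested.

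Replicate letters shared only a name: over 10 comparisons, correlations between same-letter libraries ran from -0.28 to 0.18, and 6 of 39 libraries correlated best with their own letter. With a replicate block 21 of 24 counts stayed within 1.5 times, and the others were 20 for the difference between times in kidney, 242 for KO liver at CT16-20 and 7 for the genotype difference in response at CT16-20. Light-dark libraries with matching letters were taken as 1 mouse, and without this block all 3 tissue counts were higher but within 1.5 times. Correlations between libraries so matched were weak, with means of 0.05 for liver and kidney, -0.01 for liver and lung and 0.06 for kidney and lung, and 11, 2 and 7 of 16 mice matched themselves best.

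Without the 3 lung control libraries the lung counts were 1872 at ZT4-8 and 2392 at ZT16-20, 19 for the difference between times and 29 for time, and without their mice the tissue counts were 1248 for liver and lung and 488 for kidney and lung, and the cause was not tested. Counts thinned to 1 depth stayed within 1.5 times in 8 of 8 constant-dark comparisons and were lower in 7, so depth limits how many genes are called. At a threshold of 0.01, light-dark and constant-dark WT liver shared 413 calls, and 38 genes were called in 1 direction in all 6 light-dark comparisons.

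Leaving out single libraries gave 651 to 914 called genes in light-dark liver at ZT4-8, 1494 to 1697 at ZT16-20, 148 to 220 for the difference between times and 346 to 486 for time. The ranges were 342 to 1017, 521 to 757, 23 to 155 and 57 to 372 in kidney, and 2149 to 2538, 2176 to 2437, 19 to 38 and 75 to 167 in lung. In darkness they were 615 to 999, 585 to 710, 68 to 197 and 175 to 341 in WT, and 287 to 556, 167 to 309, 1 to 13 and 0 to 1 in KO. They were 119 to 339 and 2 to 10 for the genotype difference in response, 228 to 473 and 78 to 176 for genotype in air, and, without single mice, 515 to 904, 1397 to 1698 and 662 to 847 for tissues. Among named genes, 14102 values kept direction and side of the threshold, 289 passed it newly and 163 lost it. Of the counts of list members, 2014 stayed within 1.5 times and 202 did not. With an estimated correlation 184 passing set tests no longer passed, and 647 kept their side. Whether rises or falls were more numerous changed in 11 of 27 comparisons under at least 1 alternative other than leaving out single libraries, all with reported counts at most 1.21 times apart. No called named gene changed sign under RLE, no filter, DESeq2 or a changed block, nor without any single library or mouse. Without the 3 mice, Fam25c, chosen after its values were seen, changed from 3.63 to -0.26 between liver and lung and lost its call, and no other of the 1619 called genes changed sign. In simulated data at these depths 19 to 76% of log2 changes of 1 were called, so small changes can be missed.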

Other observations

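All 4 tests of time-of-day differences below were chosen only after the pattern was seen.

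Differences between times of day may be smaller at 6% than at 21% oxygen, a hypothesis from the opposite responses of Dbp and Arntl at the 2 times. Dbp and Arntl were left out of the tests. To avoid choosing genes on the libraries tested, genes called for time in air in 1 liver experiment were taken to the other. Those of WT liver in darkness were taken to kidney and lung. All were aligned to their direction in air. Only genes with a time difference in air could enter, so the tests say nothing about differences that arise at 6% oxygen. In light-dark liver the median difference of 307 such genes was 0.41 in log2 units in air and 0.22 at 6% oxygen, smaller in 195 (exact two-sided permutation p = 0.000816, adjusted p = 0.0033). In WT liver in darkness it was 0.34 and 0.05 over 539 genes, smaller in 389 (exact permutation p = 0.00204, adjusted p = 0.0041). Over 6 clock-list genes called for time in WT liver in darkness it was 2.35 and 1.46 in kidney, smaller in 3 (exact permutation p = 0.160, adjusted p = 0.16), and 1.59 and 1.24 in lung, smaller in 4 (exact permutation p = 0.0657, adjusted p = 0.088), so the hypothesis did not pass in kidney or lung and stays open there. The light-dark tissues came from the same mice, so these are not 3 independent results. A shift of clock phase, a fall of amplitude and an effect of feeding during the exposure remain untested.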
